A study of Mus musculus with 6 samples.

How the data were processed

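Total RNA from proliferating MEFs was depleted of rRNA and made into indexed libraries with the ScriptSeq Complete Gold kit, per the labels' protocols. The submitters' processing notes name the mouse build mm9, STAR 2.5.0a, StringTie 1.3.2 and DESeq2, without giving their roles. The authors deposited 1 table of whole-number counts for the 6 libraries, with 1 row per UCSC-style transcript ID. The counts are not normalized: their totals ran from 14325677 to 20525072 per library. How the counts were derived, the strand setting and any filter are not given in the sources used here. Because a row is a transcript ID and not a gene, reads that fit several transcripts of a locus can be divided among IDs or counted more than once. Which was done is not given in the sources used here, and the values of overlapping or near-identical transcripts are uncertain. Among IDs with a mean above 50 counts, 13 had exactly the same counts as another ID in all 6 libraries. The table held 0 columns of other samples.

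The reference in hand was the GENCODE M21 annotation and gene tables of the mouse build GRCm38, which is not the build named by the submitters. After the version suffix was removed, 0 of 55419 IDs matched an entry of its gene name, RefSeq, MGI or Entrez tables. No coordinates or gene names were therefore used. The tests fixed before the data were examined for 30 gene lists, for Rb1 and the condensin subunits by name, and for genes with a divergent partner within 1000 bp could not be run.

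Groups and replicate numbers were taken from the sample titles. The labels do not say whether the replicates came from separate embryos, so p-values measure the spread between these libraries, which may be in part technical. IDs were kept by edgeR's filterByExpr with its defaults (about 10 counts in 3 libraries and 15 in total), which left 22085 and set aside 12235 others with a count above 0. Libraries were scaled by TMM, and Rb1L/L was compared with Rb1+/+ by the edgeR 4.0.16 quasi-likelihood F test, 2-sided, in R 4.3.3, over all 6 libraries with genotype as the only term. P-values were adjusted by Benjamini-Hochberg over all IDs tested, with a threshold of 0.05. Standard errors of log2 fold changes were the absolute fold change divided by the square root of F. CPM values are counts scaled by the TMM-adjusted library size, and log2 CPM values used a prior count of 2. Ratios of summed counts carry exact Poisson 95% intervals and shares carry exact binomial (Clopper-Pearson) 95% intervals.

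The rule for naming transcripts was fixed before the data were examined. It took IDs with a gene symbol, an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between genotypes. These were ranked by fold change, and the smallest unadjusted p was used only where few passed. As no ID had a symbol, the 2 IDs per direction with the smallest unadjusted p, a mean of at least 1 CPM and no overlap were named instead. They were named whether or not they passed the adjusted threshold, which departs from the planned rule. The IDs next to the named ones in serial order are described because their values bear on them, a choice made after their values were seen.

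The design text speaks of pairs of MEFs without saying that a replicate number marks a pair, so the replicate number was left out of the model and used as a block in an alternative. The other alternatives were DESeq2 1.42.0 on all rows with its default filtering and scaling, limma-voom (limma 3.58.1), other scalings, other filters, leaving out the 20 IDs with the largest counts, a threshold of 0.1, and leaving out each library in turn. Robust estimation of the quasi-dispersion, a minimum mean count of 100, and DESeq2 on the IDs that passed the edgeR filter were added after seeing the data. The tests were checked on simulated counts for the 22085 IDs, with the means, library sizes and dispersions of the real data and 50 IDs changed at each of 4 fold sizes. edgeR recovered 2% of the IDs changed 2-fold, 4% of those changed 4-fold, 38% at 8-fold and 20% at 16-fold, with 1 unchanged ID called. DESeq2 recovered 2%, 28%, 72% and 62%, with 162 unchanged IDs called. The 2-fold and 8-fold changes were all rises in Rb1L/L, and the 4-fold and 16-fold changes all falls. Size and direction cannot be told apart here. With a coefficient of variation set to 10%, edgeR recovered 90% of the 2-fold changes among the same number of IDs.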

Results

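RNA abundance was measured by sequencing of rRNA-depleted total RNA from mouse embryonic fibroblasts (MEFs), primary connective-tissue cells grown out of embryos, here from E13.5 embryos and harvested while proliferating at passage 4. The 6 libraries fell into 2 genotypes of Rb1, the gene of the retinoblastoma protein pRb, a regulator of entry into the cell cycle. There were 3 wild-type (Rb1+/+) libraries and 3 libraries from cells homozygous for the allele that the labels call L (Rb1L/L). The series title places the comparison in a study of condensin II at pRb-bound promoters and of genes arranged as divergent pairs. The question addressed here was which transcripts differed in abundance between the 2 genotypes.

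The table held 55419 rows, each a UCSC-style transcript ID with a whole-number count per library. Totals were 20525072, 20158591 and 17674522 counts in Rb1+/+ replicates 1, 2 and 3, and 16432237, 15915273 and 14325677 counts in Rb1L/L replicates 1, 2 and 3. Each Rb1L/L library was therefore shallower than each Rb1+/+ library. Between 25820 IDs (Rb1L/L replicate 2) and 28902 IDs (Rb1+/+ replicate 1) had a count above 0, and 21099 IDs had no count in any library. The file pairs no ID with a gene name, and 0 of the 55419 IDs matched the gene tables used here. The transcripts of Rb1, of the condensin subunits, of the E2F-regulated cell cycle genes and of divergent gene pairs were therefore not analysed here, and single transcripts are given by ID without a position.

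A single ID dominated 4 of the libraries. It took 9.19% of all counts in Rb1+/+ replicate 1 (exact 95% interval 9.17% to 9.20%), 9.51% in replicate 2 (9.50% to 9.53%), 9.02% in replicate 3 (9.01% to 9.04%) and 9.06% in Rb1L/L replicate 1 (9.04% to 9.07%). Its share was 0.115% in Rb1L/L replicate 2 (0.113% to 0.116%) and 0.452% in Rb1L/L replicate 3 (0.449% to 0.456%). Another abundant ID took between 1.31% and 1.58% of the counts in those same 4 libraries, 0.00827% in Rb1L/L replicate 2 and 0.0456% in Rb1L/L replicate 3. Among the 100 IDs with the largest mean counts, these 2 were the only ones whose counts, relative to the library total, differed more than 4-fold between the highest and the lowest library. The intervals cover counting error at most. They treat reads as independent molecules, which PCR copies are not, so they may be too narrow.

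The Rb1+/+ libraries resembled one another more than the Rb1L/L libraries did. Over the 22085 IDs that passed the abundance filter, Pearson correlations across IDs of log2 CPM (counts scaled to the effective library size) were 0.81 to 0.85 within Rb1+/+ and 0.75 to 0.78 within Rb1L/L. Between the genotypes they ranged from 0.76 to 0.80, and the mean between genotypes (0.777) lay above the mean within Rb1L/L (0.766). Rb1L/L replicate 1 correlated at 0.797, 0.802 and 0.795 with Rb1+/+ replicates 1, 2 and 3. Its correlations with Rb1L/L replicates 2 and 3 were lower, at 0.783 and 0.764. The mean correlation within genotypes exceeded that between genotypes by 0.0178. This was the largest value among the 10 ways to split the 6 libraries into 3 and 3, so the exact one-sided permutation p was 0.1, the smallest this design allows. The median SD between replicates was 0.39 log2 units in Rb1+/+ and 0.48 in Rb1L/L (n = 3 each). Each Rb1L/L library was also shallower, and how far depth shaped these SDs and correlations was not tested. Across all IDs the common biological coefficient of variation was 0.726.

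Of the 22085 IDs tested, 2 were lower in Rb1L/L and 0 were higher at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). The first, uc007cyd.1, fell from 185 ± 38.8 CPM in Rb1+/+ to 9.06 ± 1.93 CPM in Rb1L/L (SD, n = 3 each), a log2 fold change of -4.35 ± 0.25 (SE; edgeR adjusted p = 0.0464). Its lowest Rb1+/+ value was 154 CPM and its highest Rb1L/L value 11.3 CPM. The second, uc009orl.1, fell from 14.96 ± 2.61 CPM to 0.248 ± 0.0121 CPM (SD, n = 3 each), a log2 fold change of -5.87 ± 0.35 (SE; edgeR adjusted p = 0.0464). The Rb1L/L value rested on 4 counts in each library, against 240, 310 and 275 counts in the Rb1+/+ libraries. From the summed counts the ratio of Rb1+/+ to Rb1L/L for uc009orl.1 was 59.7 (exact 95% interval for counting error 34.0 to 116).

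No ID passed the threshold in the other direction. The smallest unadjusted p among IDs with higher values in Rb1L/L belonged to uc007mxw.2, which measured 0.0536 ± 0.0503 CPM in Rb1+/+ and 70.2 ± 39.4 CPM in Rb1L/L (SD, n = 3 each; edgeR adjusted p = 0.0865). Its Rb1+/+ value came from 3 counts over the whole group against 3350 counts in Rb1L/L, a ratio of 1285 with an exact 95% counting interval of 439 to 6234. The ID next to uc007mxw.2 in serial order took the opposite course, at 101 ± 34.1 CPM in Rb1+/+ and 0 counts in each Rb1L/L library (edgeR adjusted p = 0.0882). Summed over both IDs, the values were 101 ± 34.1 CPM and 70.2 ± 39.4 CPM (SD, n = 3 each), a difference within the spread between replicates. For uc007bgd.1 the values were 0.106 ± 0.0477 CPM (6 counts in all) and 7.27 ± 2.64 CPM (SD, n = 3 each; edgeR adjusted p = 0.0912), a count ratio of 67.3 with an exact 95% counting interval of 30.6 to 185. The next ID after uc007bgd.1 also measured lower in Rb1L/L (log2 fold change -2.10, unadjusted p = 0.00882, edgeR adjusted p = 0.441), but the sum of both was still 1.90 ± 0.851 CPM in Rb1+/+ and 7.68 ± 2.73 CPM in Rb1L/L (SD, n = 3 each). For uc007cyd.1, sums with the previous and the next ID were 194 and 187 CPM in Rb1+/+ and 14.1 and 11.1 CPM in Rb1L/L. For uc009orl.1, the sum with the previous ID was 16.6 ± 3.94 CPM in Rb1+/+ and 1.304 ± 1.16 CPM in Rb1L/L. The next ID was more abundant and measured 181 CPM in each genotype. Its sum with uc009orl.1 was 196 ± 31.2 CPM in Rb1+/+ and 182 ± 43.7 CPM in Rb1L/L, a difference within the spread. The SD of the next ID (30.5 and 43.7 CPM) exceeded the whole value of uc009orl.1. This sum therefore cannot show whether counts moved between these IDs.

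**Figure D1:**
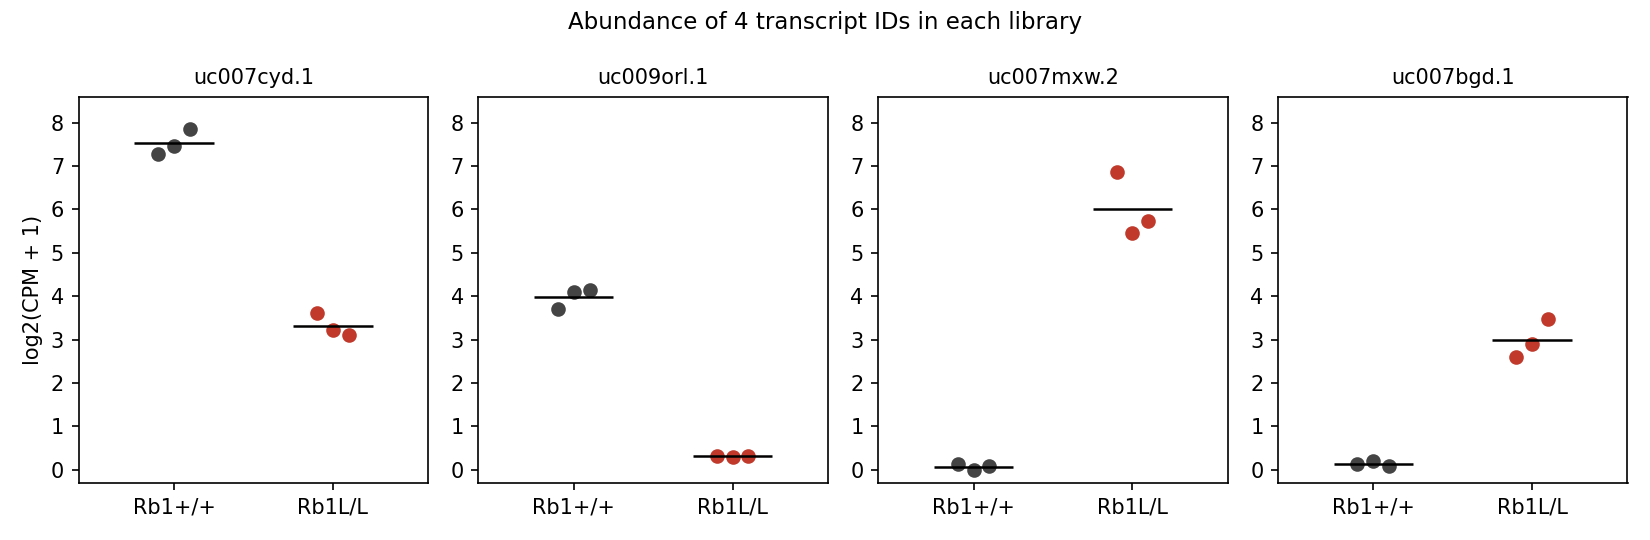
Abundance of 4 transcript IDs as log2(CPM + 1) on the vertical axis, by genotype on the horizontal axis. Each point is a library (n = 3 per genotype) and each bar the group mean. The genotypes do not overlap for any of the 4 IDs, as the naming rule required. Of these, uc007cyd.1 and uc009orl.1 passed the adjusted threshold of 0.05.

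Over all 6 libraries, more IDs than the nominal rate fell under the unadjusted threshold. An unadjusted p under 0.05 was reached by 1843 IDs (8.35%), of which 903 had higher and 940 lower values in Rb1L/L, against 1104 IDs at the nominal rate. The share varied with the library left out: it was 1171 of 23390 IDs (5.01%) without Rb1+/+ replicate 1 and 1313 of 23459 IDs (5.60%) without Rb1+/+ replicate 2, against 6.57% to 9.85% without each of the other libraries. Each of these fits used fewer libraries and another set of IDs. Lost power may account for part of a fall, so a share near 5% does not show that the excess vanished. With all 6 libraries, scaling by library size alone moved the median log2 fold change of all IDs from -0.02 to 0.11. It turned the 903 higher and 940 lower IDs into 1311 higher and 530 lower. In 3888 IDs (17.6%) the CPM values of the genotypes did not overlap, where a chance order of 3 against 3 gives 10% on average. IDs of a library are not independent, and this share was not counted for other splits, so its spread by chance is unknown. Abundance mattered for the count at an unadjusted p under 0.05 (edgeR). An unadjusted p under 0.05 was reached by 4.03% of the 1911 IDs with a mean under 1 CPM, 5.81% of the 10437 IDs at 1 to 10 CPM, 10.7% of the 8032 IDs at 10 to 100 CPM and 17.5% of the 1705 IDs above 100 CPM. The differences among the most abundant IDs were small. Above 100 CPM the median absolute log2 fold change was 0.23, 43 IDs (2.52%) differed more than 2-fold, and the smallest adjusted p was 0.157 (edgeR). Of the 299 IDs in that class with an unadjusted p under 0.05, 128 had higher and 171 lower values in Rb1L/L. Between 1 and 10 CPM the median standard error of a log2 fold change was 0.61, against 0.17 above 100 CPM.

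**Figure D2:**
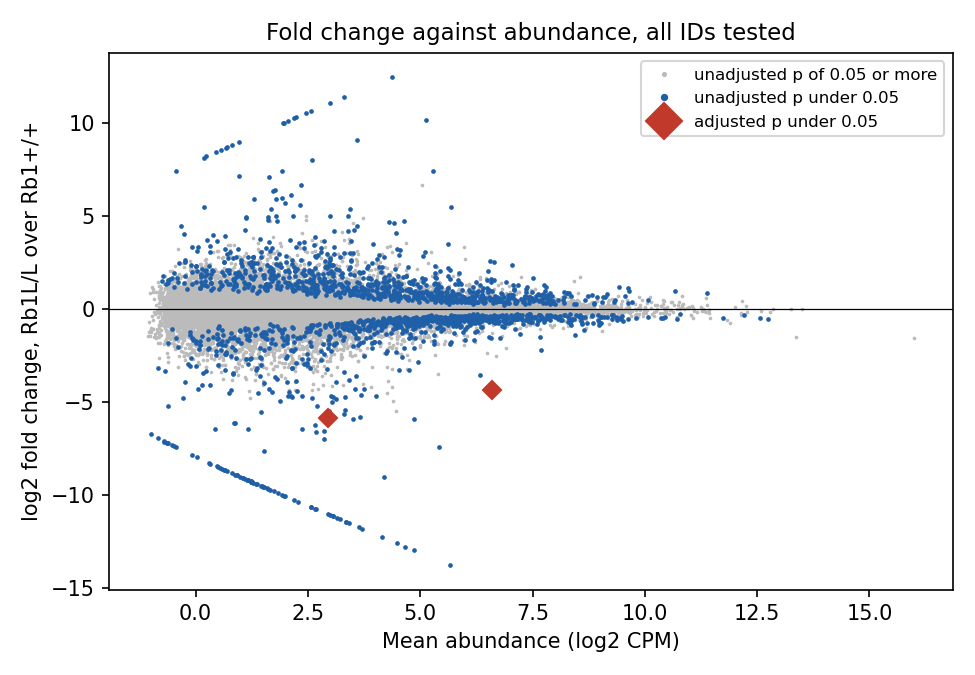
Log2 fold change of Rb1L/L over Rb1+/+ (vertical axis) against mean abundance in log2 CPM (horizontal axis) for 22085 transcript IDs. Grey and blue points have an unadjusted p above or below 0.05, the 2 red diamonds passed the adjusted threshold, and the diagonal lines of points at the outer edges are IDs at 0 counts in all libraries of a genotype, whose fold changes have no fixed size.

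The count of calls differed between tools. DESeq2, run with its own filter and scaling (21005 IDs with an adjusted p), called 804 IDs (384 higher and 420 lower in Rb1L/L), including both edgeR calls. On the IDs that passed the edgeR filter it called 748 of the 21810 to which it gave an adjusted p. limma-voom called 0 of 22085 (2130 IDs, 9.64%, at an unadjusted p under 0.05). With no abundance filter edgeR called 0 of 34320 IDs (2328, or 6.78%, at an unadjusted p under 0.05; adjusted p = 0.0586 for both IDs), and scaling by library size alone ended the call of uc009orl.1 (adjusted p = 0.0522). Leaving out any 1 of the 6 libraries ended both edgeR calls, with adjusted p-values from 0.05004 to 0.214 for uc007cyd.1 and from 0.0657 to 0.264 for uc009orl.1. Using the replicate number as a block also ended both (edgeR adjusted p = 0.693 for each), though the numbers were not taken to mark pairs.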

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

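The alternatives of minimum mean count, robust dispersion and DESeq2 on the edgeR-filtered IDs were chosen after seeing the data, and the others were fixed before the data were examined. The count of 2 calls was 2 with RLE or upper-quartile scaling, the same 2 IDs each time. It was 804 with DESeq2, 0 with limma-voom, 1 with library size only, 0 with no filter and 4 with at least 1 CPM in 3 libraries. It was 5 without the 20 largest IDs, 16 (2 higher, 14 lower) at a threshold of 0.1, 5 with robust dispersion and 6 with a mean count of at least 100. For the DESeq2 count, the filter and IDs at 0 in a genotype were examined, as given below. The cause of the other differences was not tested, except that the unfiltered fit adjusted over more IDs (34320) and the stricter filters over fewer (20087 and 12596). DESeq2 gave 3114 of 33140 IDs (9.40%) at an unadjusted p under 0.05, against 1843 of 22085 (8.35%); on the IDs that pass the edgeR filter it gave 748 calls. Leaving out 1 library gave 0 to 2 calls and 1171 to 2316 IDs at an unadjusted p under 0.05; the 2 calls without Rb1L/L replicate 1 were other IDs, and the lowest value came without Rb1+/+ replicate 1. The replicate block gave 0 calls and 1575 IDs at an unadjusted p under 0.05 (adjusted p = 0.693 for all 4 named IDs); same-numbered libraries did not deviate together (r of their deviations across IDs 0.013, -0.028 and 0.0011), and not every library correlated best with its own number, so the numbers were not taken as pairs. The direction of the 4 named IDs was kept in each alternative that tested them, with log2 fold changes from -4.54 to -4.18 for uc007cyd.1, -6.01 to -5.72 for uc009orl.1, 9.61 to 10.93 for uc007mxw.2 and 5.68 to 6.35 for uc007bgd.1, which was not tested at a mean count of at least 100. The naming rule required no overlap between genotypes, so a reversal was hardly possible. The alternatives for rows with a gene symbol, sex-linked genes, gene lists and divergent pairs were not run, because no ID could be matched to a gene. In the simulation with the real dispersions, edgeR recovered 2% of 2-fold rises and 4% of 4-fold falls in Rb1L/L. With the same means and library sizes and a coefficient of variation of 10%, it recovered 90% of the 2-fold rises. Depth itself was not varied, and the median standard error fell from 0.80 under 1 CPM to 0.17 above 100 CPM.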

Other observations

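Tests of neighbouring IDs in opposite directions, of the dominant ID and of IDs at 0 in library triples were chosen after seeing the result. So were the counts over other splits of edgeR calls and of IDs at an unadjusted p under 0.05. No prediction was written beforehand for the split count above 100 CPM. The labels place no sample outside the 2 genotypes. Among the IDs tested, those at 0 counts in all libraries of a genotype were unequal between the genotypes. With a minimum of 50 counts in each library of the other genotype, 42 IDs were at 0 in all 3 Rb1L/L libraries and 9 were at 0 in all 3 Rb1+/+ libraries. Other triples of libraries gave 6 to 32 such IDs, the 32 being present in Rb1+/+ replicates 1 and 2 and Rb1L/L replicate 1 and at 0 in the remaining 3. Among these other triples, those with both Rb1+/+ replicates 1 and 2 gave 22 to 32, and the rest gave 6 to 15.

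Changes of more than 8-fold with an unadjusted p under 0.01 were seen in 174 IDs, 61 higher and 113 lower in Rb1L/L, and 93 of them were at 0 in a whole genotype. Lower depth in Rb1L/L is argued against as the whole cause, since 35.1% of them (exact 95% interval 28.0% to 42.6%) were higher in Rb1L/L. A neighbour in the serial order of the IDs was tested for 131 of the 174 IDs. Of these, 26.7% (35 IDs) had a neighbour that changed the opposite way at an unadjusted p under 0.05 (edgeR), against 9.92% with one that changed the same way. Random neighbours of like abundance gave a median of 5.34% (upper end of the central 95% range 9.92%). A pair with large changes in both IDs, such as uc007mxw.2 and the ID next to it, counted once for each ID. Random neighbours were drawn without such pairing, so their range may be too narrow. Among 739 IDs with changes up to 2-fold, an unadjusted p under 0.05 and a tested neighbour, the shares were 4.06% opposite and 9.47% the same. Counts moving between transcripts of a locus could give opposite neighbours for part of the large changes, if serial neighbours share a locus. That was not tested. A real change of transcript and a change in how reads were divided stay open. Deviations within genotypes gave a median r of -0.17 between opposite neighbours, not separable from random IDs (lower end of their central 95% range -0.22). This correlation can decide little, because IDs at 0 in a whole genotype do not vary there. Adding the opposite neighbour lowered the median absolute log2 change from 5.90 to 0.45. Adding a random ID changed the opposite way gave 0.64 (lower end of the central 95% range 0.47), so most of that drop needs no shared locus. The value with real neighbours lay just below the random range. Pairs with large changes in both IDs again counted once for each ID, so that range may be too narrow.

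The dominant ID took 9.06% of counts in Rb1L/L replicate 1, against 9.02% in Rb1+/+ replicate 3, while its share was low in Rb1L/L replicates 2 and 3; with 1 library deciding, a role of the genotype stays open. Both called IDs, 2 of 2, kept their call when the 20 largest IDs were left out, and 5 IDs passed in all. The counts of the dominant ID were therefore not needed for the 2 calls. TMM scaling already trims IDs with extreme ratios, so the test was a weak one. It cannot address a difference between libraries that the dominant ID may mark. Scaling by library size alone, where the dominant ID counts in full, ended the call of uc009orl.1 (edgeR adjusted p = 0.0522). A difference in library preparation or rRNA depletion, or between the embryos, also stays open and was not tested, since the labels give no batch and the ID has no name here.

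DESeq2 called 802 IDs that edgeR did not; 128 of these had not passed the edgeR filter, and all 674 others had an unadjusted edgeR p under 0.05. On the edgeR-filtered IDs DESeq2 still called 748, so the filter is argued against as the main cause of the gap. IDs at exactly 0 in a whole genotype made up 20.3% of the 802, so they are argued against as the main cause of the gap. They were still more frequent there than among the 22085 IDs edgeR tested. Of those, 75 were at 0 in all Rb1L/L libraries and 19 in all Rb1+/+ libraries. IDs with only a few counts in a genotype were not counted, so a part of near-0 IDs in the gap stays open. In the simulation with the real dispersions, 162 unchanged IDs passed with DESeq2 and 1 with edgeR. Of the 50 changed IDs per fold size, DESeq2 recovered 2% at 2-fold, 28% at 4-fold, 72% at 8-fold and 62% at 16-fold. Unchanged IDs were therefore the larger part of its simulated calls, well above the nominal rate. That share rests on the number of changed IDs set in the simulation, so how many of the 802 are false calls stays open.

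The 10 splits of the 6 libraries are too few for a share under 0.05. In each of these counts the real split was the highest, 1 of 10. It gave 2 edgeR calls against at most 1 in another split, 1843 IDs at an unadjusted p under 0.05 against 1164, 174 large changes against 144, and 804 DESeq2 calls against 431. Without Rb1+/+ replicate 1 the genotypes gave 1171 of 23390 IDs (5.01%) at an unadjusted p under 0.05 (edgeR). That fit used fewer libraries and another set of IDs, so its count is not comparable with the splits. Among IDs above 100 CPM the real split gave 299 at an unadjusted p under 0.05 against at most 190. Other splits that kept Rb1+/+ replicates 1 and 2 together gave 792 to 1164 IDs at an unadjusted p under 0.05 (edgeR). The remaining splits gave 450 to 752. The real split also keeps these replicates together, so its rank cannot be assigned to genotype alone.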
